A study of Homo sapiens with 28 samples.

How the data were processed

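The cells were CHL-1, an established human melanoma line. Per the labels' protocols they were grown in DMEM with fetal calf serum, seeded on the day before treatment, and given BAY1238097, an inhibitor of the bromodomains of the BET proteins, at 75 nM or 468 nM, or the solvent DMSO, for 4 h or 24 h. The submitters gave the lower dose as the IC50 of the compound and the higher dose as its IC90. Total RNA was biotin-labelled and hybridised to 28 Affymetrix arrays of the whole-transcript Human Gene type. The groups held 4 arrays for DMSO at 4 h, 4 for DMSO at 24 h, and 5 for each dose at each time. Replicate numbers only name an array within its group, in the order in which the samples were listed. Nothing in the labels says that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

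The authors deposited intensity values on a linear scale for 53617 probe sets, with 0 missing values. Per the submitters' processing notes the probe sets were summarised with RMA (robust multi-array average), which subtracts background, equalises the intensity distributions of all arrays and combines the probes of a set. The RMA software version and the genome build behind the probe sets are not given in the sources used here. Median log2 values lay between 2.44 and 2.49 on every array, so each value is relative to the distribution of its own array, and a change shared by most transcripts would not be seen. The deposited intensity values were transformed to log2 before any test, since limma's model assumes a log scale. Depth of the kind that sequencing has is not defined for arrays, and the number of arrays limits the precision.

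Probe sets were named from a table pairing them with the platform's gene annotation. Of all probe sets, 23871 had 1 gene symbol, 1842 had several and 27904 were not listed in the table and stay unnamed here. Symbols were brought up to date with an NCBI RefSeq gene table of the assembly GRCh38.p14, for 22569 probe sets through the gene ID, for 733 by a current symbol and for 565 through an older symbol, while 4 kept the table's symbol. No coordinates are printed, because the build behind the probe sets is unknown, and that table was otherwise used only to tell which genes neighbour each other. A gene was represented by the probe set with the highest mean over all arrays among those naming it alone. That gave 22357 genes, of which 663 had more than 1 probe set. Genes were tested when their log2 value was above 5 on at least 4 arrays, which left 9285. CDKN1A and MITF did not pass this filter. The planned check of 3 prime against 5 prime signal in control probe sets was not run, because control probe sets are not named in the table used.

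Differential expression was tested with limma 3.58.1 in R 4.3.3, and tables were prepared with Python 3.11.15. Linear models with 6 group means were fitted to all 28 arrays, with 22 residual and 3.84 prior degrees of freedom, followed by moderated tests and Benjamini-Hochberg adjustment within each comparison. A gene was called changed at an adjusted p below 0.05. The comparisons were each dose against DMSO at the same time, 468 nM against 75 nM at each time, the difference of each dose's effect between 24 h and 4 h (an interaction), and DMSO at 24 h against 4 h. Values in the text are log2 fold changes with their standard error, unless a mean and SD of log2 intensity is named.

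Lists of genes were fixed before the data were examined, as were the tests of genes and lists, the filter and all alternatives except those named as added. There were 24 lists: reported BET inhibitor markers, BET proteins and the P-TEFb complex, histone genes, MYC family and partners, ribosome biogenesis and MYC target genes, G1/S regulators, DNA replication genes, mitosis genes, CDK inhibitors and p53 target genes, BCL2 family and apoptosis genes, melanocyte lineage genes, undifferentiated melanoma state genes, AP-1 and immediate early genes, MAPK feedback genes, NF-kB target and cytokine genes, interferon-stimulated genes, extracellular matrix and adhesion genes, cholesterol synthesis genes, amino acid and unfolded protein stress genes, lysosome and autophagy genes, glycolysis and hypoxia genes, heat shock genes, receptor tyrosine kinases and growth factors, and reference genes. A further 4 lists held markers of keratinocytes, fibroblasts, leukocytes and endothelial cells. A list with at least 5 measured members was compared with all other tested genes by camera, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Camera was run again with a correlation estimated for each list, and fry was an alternative that tests a list's members alone. Counts of changed members are given over all genes tested and with p-values adjusted over the list alone. Many members of some lists did not pass the filter. Measured were 15 of 27 CDK inhibitors and p53 target genes, 8 of 32 NF-kB target and cytokine genes and 8 of 24 melanocyte lineage genes. CDKN1B was the only CDK inhibitor among the 15.

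The genes named in the text followed a fixed rule. For 468 nM against DMSO at each time they were the 8 largest rises and the 8 largest falls among changed genes whose treated arrays all lay above, or all below, every DMSO array of that time. The same rule took 4 rises and 4 falls for 75 nM against DMSO, for 468 nM against 75 nM and for DMSO over time, and the interactions took the 4 largest positive and the 4 largest negative values among changed genes. From each list described, up to 4 members with the smallest adjusted p could be named. MYC, HEXIM1, BRD2, BRD3, CCND1 and FOSL1 were named against DMSO whatever their values.

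Alternatives were moderation with a mean trend and robust variances, array weights, a fit with only the groups compared, a replicate block, the mean of all probe sets of a gene, no filter, a filter at a log2 value of 7, centring each array on its median, repeated quantile normalization, a shift by the reference genes, a further threshold of a 2-fold change, an adjusted p below 0.01, and leaving out each array in turn. An alternative chosen after seeing the data took the 4 h arrays of code sets 2 and 4 as a block. The replicate block came from the sample codes in the labels, which run through the groups at a spacing of 26 and so fall into sets. Whether such sets pair the samples was checked by correlating deviations from group means over genes. Every pair correlated above 0.1 for 75 nM with DMSO at 4 h (0.108 to 0.324), 468 nM with DMSO at 4 h (0.159 to 0.277) and 468 nM with 75 nM at 4 h (0.103 to 0.345), so the sets were taken as pairing the 4 h samples of these comparisons. Within groups no pair of arrays was identical, since the SD of the log2 difference between replicates was 0.613 to 0.792.

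The whole calculation was tested on simulated data in which 200 of 9285 genes were changed. At a log2 change of 1 the test recovered 85.1% of changed genes for 75 nM against DMSO at 4 h, 83.6% for 468 nM at 4 h, 82.1% for 75 nM at 24 h and 91.0% for 468 nM at 24 h. At a log2 change of 0.5 it recovered 47.8%, 47.8%, 44.8% and 44.8% in the same order. False calls numbered 5 of 160 calls, 10 of 164, 4 of 154 and 6 of 163. A simulated shift of 0.3 in the DNA replication genes at 468 nM and 24 h was found in 20 of 20 simulations, and 0 of 460 tests of other lists were called by camera. The simulated genes varied independently of each other. These simulations therefore do not show how often camera would wrongly call a list of correlated genes.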

Results

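Gene expression was measured on 28 arrays of CHL-1 melanoma cells to follow how transcription changed with the dose of the BET inhibitor BAY1238097 and with time. BET proteins read acetylated histones through their bromodomains and recruit the transcription elongation machinery. Cells received 75 nM or 468 nM of the compound (5 arrays per dose and time) or DMSO (4 arrays per time) for 4 h or 24 h, and 9285 genes were tested. The first principal component took 38.7% of the variance and placed the 468 nM, 24 h arrays apart from all others, and the next took 12.5%. Markers of other cell types were largely below the filter: of 10 markers each, 0 keratinocyte and 0 endothelial markers were measurable, with FBLN1 the 1 fibroblast marker and CD68 the 1 leukocyte marker above it. All changes are relative to the normalized distribution of each array. When arrays were shifted to hold the 9 measured reference genes level, the median log2 change over all genes moved. It became -0.153 for 468 nM against DMSO at 4 h, -0.13 for 468 nM against 75 nM at 4 h, 0.139 for DMSO over time and 0.115 for the interaction at 468 nM. The changes reported below are those without this shift, so their sizes in these comparisons depend on the scaling.

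**Figure D1:**
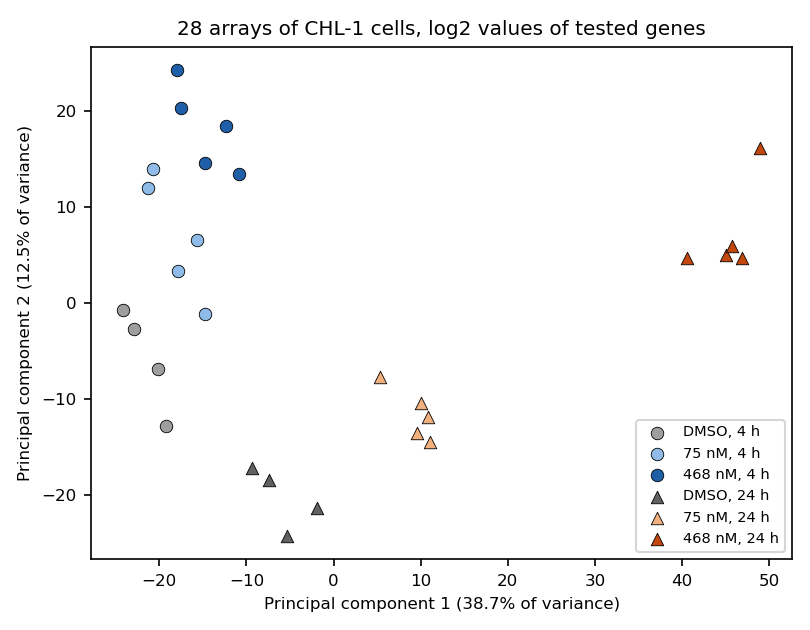
Each point is 1 of the 28 arrays, placed by its scores on the first (x axis, 38.7% of variance) and the next (y axis, 12.5%) principal component of log2 values; circles are 4 h, triangles 24 h, grey DMSO, light shades 75 nM and dark shades 468 nM. The 468 nM, 24 h arrays lie at the far right, and 1 of them (replicate 2) lies apart on the y axis at 16.12.

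At 75 nM and 4 h, HEXIM1, an inhibitor of the elongation kinase P-TEFb whose RNA is a known readout of BET inhibition, rose by 0.85 ± 0.13 on the log2 scale, from 7.07 ± 0.21 (SD, n = 4) to 7.92 ± 0.11 (SD, n = 5; limma adjusted p = 6.28e-04). BRD2, itself a BET protein, rose by 0.49 ± 0.08 (adjusted p = 0.00108). The largest rises were those of FGF18, a fibroblast growth factor (1.69 ± 0.30, adjusted p = 0.00344), and SERTAD1, a CDK4-binding cofactor (1.05 ± 0.16, adjusted p = 7.92e-04). FGF18 had a mean of only 3.08 in DMSO, near the median of all probe sets, so the size of its rise is uncertain. Then came MKNK2, a kinase of the translation factor eIF4E (0.98 ± 0.13, adjusted p = 2.08e-04), and BAIAP2, an adaptor of the actin cytoskeleton (0.96 ± 0.12, adjusted p = 7.74e-05). Among genes whose arrays did not overlap between the groups, the largest falls were those of TRAF1, an adaptor of TNF receptors (-1.44 ± 0.32, adjusted p = 0.0285), and PLAAT5 (-1.42 ± 0.34, adjusted p = 0.0473). They were followed by the growth factor FGF7 (-1.26 ± 0.26, adjusted p = 0.0134) and the gap junction protein GJD2 (-1.15 ± 0.18, adjusted p = 8.38e-04). MYC, at -0.41 ± 0.13 (adjusted p = 0.222), did not pass the test. Neither did CCND1 (-0.25 ± 0.12, adjusted p = 0.579), FOSL1 (-0.22 ± 0.15, adjusted p = 0.808) or BRD3 (0.13 ± 0.14, adjusted p = 0.914).

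Among the fixed lists, NF-kB target and cytokine genes were lower as a group at this dose and time (median -0.422, camera adjusted p = 7.43e-05, and adjusted p = 0.00515 with an estimated correlation). Of 8 measured members 2 fell, and 4 when adjusted over the list alone. TNFAIP3, a feedback inhibitor of NF-kB, fell by 1.05 ± 0.13 on the log2 scale (adjusted p = 1.07e-04), and CSF1, a macrophage growth factor, fell by 0.87 ± 0.17 (adjusted p = 0.00907). CDK inhibitors and p53 target genes were higher (median 0.157, camera adjusted p = 0.0308), with 2 of 15 members risen, and 3 when adjusted over the list alone, although the list had an adjusted p = 0.0512 with an estimated correlation and 0.0634 with the filter at 7. Its 2 risen members were GADD45A, a stress-induced growth arrest gene (0.88 ± 0.16, adjusted p = 0.00545), and the sestrin SESN1 (0.68 ± 0.16, adjusted p = 0.0392). CDKN1B was the only CDK inhibitor of the list above the filter. SESN1 missed the threshold without 75 nM replicate 1 (0.0664), 4 (0.0868) or 5 (0.108), or without DMSO replicate 1 (0.0914), 2 (0.0961) or 3 (0.192). With the replicate block, 3 further lists passed with higher values. These were AP-1 and immediate early genes (adjusted p = 0.0163), histone genes (0.0495) and lysosome and autophagy genes (0.0495). An estimated correlation was not tried with the block. Without the block, few members had an unadjusted p below 0.05 by limma. They were 4 higher and 3 lower of 23 AP-1 genes, 1 of 15 histone genes and 0 of 27 lysosome and autophagy genes. Of single genes, MXD1 and JUND also passed with the block as higher and SPRY2 as lower.

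In all, limma called 63 genes changed at 75 nM and 4 h, 31 higher and 32 lower, of which 2 rose and 10 fell at least 2-fold. The count was 39 without DMSO 4 h replicate 1 and also 39 without replicate 2, 28 with no filter on dim genes, 31 with only the groups compared and 36 after the shift by reference genes. Repeated quantile normalization gave 39 higher and 28 lower. TRAF1 missed the threshold without DMSO replicate 1 (adjusted p = 0.0509), 3 (0.0632) or 4 (0.136) or 75 nM replicate 2 (0.0959), 3 (0.0591) or 4 (0.0675). PLAAT5 missed it without DMSO replicate 1 (0.184), 3 (0.234) or 4 (0.0539) or 75 nM replicate 1 (0.148), 3 (0.11), 4 (0.0868) or 5 (0.083), and FGF7 without DMSO replicate 1 (0.0595) or 2 (0.0568). Of the 14 probe sets of BRD2, 6 dim ones with a mean of 3.66 stood at -0.23 each, and the mean of all its probe sets gave 0.17 (adjusted p = 0.838).

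At 468 nM and 4 h, MYC, the growth-promoting transcription factor, fell by 1.07 ± 0.13 on the log2 scale, from 8.79 ± 0.11 (SD, n = 4) to 7.72 ± 0.20 (SD, n = 5; limma adjusted p = 2.59e-06). HEXIM1 rose by 1.67 ± 0.13 (adjusted p = 5.2e-10). The largest fall was that of the inflammatory cytokine IL6, from a mean of 7.53 (n = 4) to 4.10 ± 0.99 (SD, n = 5), a change of -3.43 ± 0.59 (adjusted p = 1.89e-04). The next falls were those of TMEM238L (-3.0 ± 0.51, adjusted p = 1.61e-04), the gap junction gene GJD2 (-2.67 ± 0.18, adjusted p = 1.03e-10) and the microRNA gene MIR568 (-2.60 ± 0.76, adjusted p = 0.0237). The means of MIR568 (2.39) and TMEM238L (2.96) at 468 nM lie near the median of all probe sets or below it, so the sizes of their falls are uncertain. The antisense RNA genes STEAP1B-AS1 (-2.27 ± 0.28, adjusted p = 1.91e-06) and IL6-AS1 (-2.15 ± 0.36, adjusted p = 1.61e-04) fell as well. So did the interferon-inducible chaperone RTP4 (-2.18 ± 0.22, adjusted p = 9.85e-08) and DIO2, which activates thyroid hormone (-2.1 ± 0.35, adjusted p = 1.43e-04). The largest rises were those of VASN, a TGF-beta-binding membrane protein (2.39 ± 0.29, adjusted p = 1.78e-06), and FGF18 (2.30 ± 0.30, adjusted p = 5e-06). Their DMSO means of 3.52 and 3.08 lie below the filter value of 5, so the sizes of both rises are uncertain. The histone genes H2BC5 (2.24 ± 0.27, adjusted p = 1.42e-06) and H3C13 (2.12 ± 0.30, adjusted p = 1.24e-05) rose to a similar extent. They were followed by SERTAD1 (2.04 ± 0.16, adjusted p = 1.35e-09), GADD45A (1.94 ± 0.16, adjusted p = 3.26e-09), BAIAP2 (1.86 ± 0.12, adjusted p = 4.9e-11) and the microRNA gene MIR3143 (1.86 ± 0.25, adjusted p = 6.75e-06). BRD2 rose by 0.58 ± 0.08 (adjusted p = 7.78e-06), and CCND1, encoding cyclin D1, fell by 0.46 ± 0.12 (adjusted p = 0.0116). BRD3 (0.20 ± 0.14, adjusted p = 0.455) and FOSL1 (-0.23 ± 0.15, adjusted p = 0.414) did not pass.

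NF-kB target and cytokine genes were lower at 468 nM and 4 h (median -0.708, camera adjusted p = 4.14e-05, and adjusted p = 0.00195 with an estimated correlation). Of 8 members 5 fell, and 5 when adjusted over the list alone, among them TNFAIP3 (-2.07 ± 0.13, adjusted p = 5.46e-11), CSF1 (-1.66 ± 0.17, adjusted p = 1.49e-07) and NFKB1, a subunit of NF-kB itself (-0.63 ± 0.13, adjusted p = 0.00128). CDK inhibitors and p53 target genes were higher (median 0.418, camera adjusted p = 1.32e-04, and adjusted p = 0.00195 with an estimated correlation). Of 15 members, with CDKN1B the only CDK inhibitor, 7 rose and 2 fell, or 8 and 2 when adjusted over the list alone. They included rises of the sestrin SESN2 (1.31 ± 0.16, adjusted p = 2.3e-06), GADD45B (0.99 ± 0.13, adjusted p = 6.13e-06) and cyclin G1, CCNG1 (0.58 ± 0.10, adjusted p = 1.61e-04). AP-1 and immediate early genes were higher too (median 0.464, camera adjusted p = 1.41e-04, but adjusted p = 0.0689 with an estimated correlation). Of 23 members 8 rose and 1 fell, or 11 and 1 when adjusted over the list alone. IER5 (1.74 ± 0.18, adjusted p = 2.02e-07), JUND (1.35 ± 0.18, adjusted p = 5.56e-06) and JUN (1.48 ± 0.20, adjusted p = 1e-05) rose, while the zinc finger factor KLF6 fell (-0.95 ± 0.12, adjusted p = 3.66e-06).

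Smaller shifts at 468 nM and 4 h passed camera but not with an estimated correlation. Histone genes were higher (median 0.401, camera adjusted p = 0.00108, adjusted p = 0.241 with an estimated correlation), with 3 of 15 risen, or 4 risen and 1 fallen when adjusted over the list alone, including H2BC5 and H2BC21 (1.38 ± 0.21, adjusted p = 5.53e-05). H2BC14 stood at -1.20 ± 0.42 (adjusted p = 0.0669), and at -1.32 (adjusted p = 0.0267) with the replicate block. Ribosome biogenesis and MYC target genes were lower (median -0.149, camera adjusted p = 0.0162, adjusted p = 0.271 with an estimated correlation), with 4 of 31 fallen, and 4 when adjusted over the list alone, such as RRS1, a ribosome assembly factor (-0.81 ± 0.21, adjusted p = 0.00996). Heat shock genes ranked higher (median 0.113, camera adjusted p = 0.0112, adjusted p = 0.0917 with an estimated correlation), with 2 of 12 risen, or 3 when adjusted over the list alone. The 2 were the co-chaperone BAG3 (0.94 ± 0.10, adjusted p = 1.44e-07) and HSP90AA1 (0.43 ± 0.11, adjusted p = 0.00718). The median of this list turned to -0.0121 after the shift by reference genes. With the filter at 7, camera's adjusted p was 0.241 for histone genes, 0.0663 for ribosome biogenesis and MYC target genes, 0.177 for heat shock genes and 0.145 for AP-1 and immediate early genes.

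No other list passed camera at 468 nM and 4 h, yet single members changed. Of 16 BCL2 family genes 3 rose and 2 fell (3 and 4 when adjusted over the list alone). The death-promoting BCL2L11 (1.12 ± 0.20, adjusted p = 3.81e-04) and PMAIP1 (1.1 ± 0.21, adjusted p = 6.67e-04) rose. The survival genes BCL2L1 (-0.70 ± 0.14, adjusted p = 0.00119) and BCL2 (-0.92 ± 0.19, adjusted p = 0.00148) fell. MXD1, which competes with MYC for its partner MAX, rose by 1.48 ± 0.19 (adjusted p = 4.29e-06). The neural crest factor SOX10 fell (-0.73 ± 0.13, adjusted p = 4.31e-04), as did ZEB2, a regulator of melanocyte identity (-1.17 ± 0.17, adjusted p = 1.95e-05). Among MAPK feedback genes 4 of 17 rose and 3 fell (4 and 6 when adjusted over the list alone), with PHLDA1 at 0.95 ± 0.20 (adjusted p = 0.00159) and SPRY2 at -0.80 ± 0.13 (adjusted p = 9.93e-05).

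Limma called 1013 genes at 468 nM and 4 h, 368 higher and 645 lower, with 83 risen and 126 fallen at least 2-fold. After the shift by reference genes the split was 196 higher and 1011 lower of 1207, and after repeated quantile normalization 475 higher and 561 lower of 1036. With the mean of all its probe sets BRD2 stood at 0.04 (adjusted p = 0.925). Its dim probe sets with a mean of 3.66 stood at -0.82 each, while those with means of 7.22 to 10.08 rose by 0.24 to 0.83. CCND1 missed the threshold without DMSO 4 h replicate 1 (adjusted p = 0.0787) or with only the groups compared (0.101), and MIR568 missed it without DMSO replicate 1 (0.0684) or 3 (0.0564) or 468 nM replicate 3 (0.073) or 5 (0.0813).

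**Figure D2:**
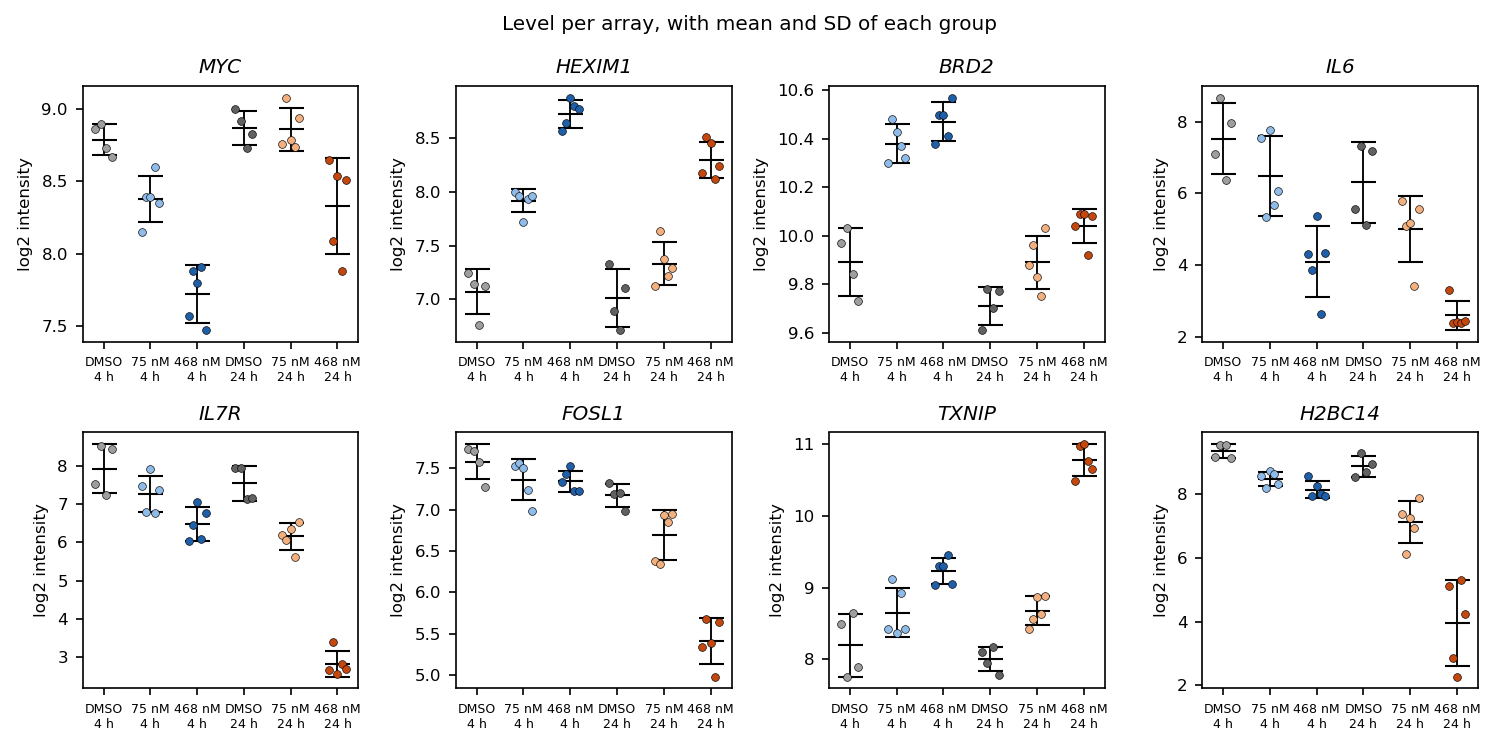
Each panel shows 1 gene, with log2 intensity on the y axis, the 6 groups on the x axis, a point for each array and the group mean with its SD. HEXIM1 is higher in every 468 nM array than in the DMSO arrays of the same time, IL7R at 24 h falls from a mean of 7.54 in DMSO to 6.15 at 75 nM and 2.82 at 468 nM, and H2BC14 at 24 h falls from 8.87 to 3.96 at 468 nM.

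The doses were compared directly at 4 h to see which changes grew with dose. HEXIM1 was higher at 468 nM than at 75 nM by 0.82 ± 0.12 (limma adjusted p = 1.3e-04), and MYC was lower by a difference of -0.65 ± 0.13 (adjusted p = 0.00308). The largest positive differences were those of VASN (1.66 ± 0.27, adjusted p = 6.43e-04) and the protocadherin PCDH10 (1.49 ± 0.27, adjusted p = 0.00202). The neuronal pentraxin receptor NPTXR (1.36 ± 0.26, adjusted p = 0.00329) and H3C13 (1.36 ± 0.28, adjusted p = 0.00576) followed. IL6 had the most negative one (-2.38 ± 0.55, adjusted p = 0.0156), with overlapping arrays. The largest negative ones without overlap were those of TMEM238L (-2.16 ± 0.48, adjusted p = 0.0104) and IL6-AS1 (-1.54 ± 0.34, adjusted p = 0.0104). GJD2 (-1.53 ± 0.17, adjusted p = 1.69e-05) and RTP4 (-1.42 ± 0.21, adjusted p = 1.47e-04) came next.

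Between doses at 4 h, CDK inhibitors and p53 target genes were higher at 468 nM (median 0.144, camera adjusted p = 8.6e-05, adjusted p = 0.00234 with an estimated correlation), with 5 of 15 higher, and 5 when adjusted over the list alone. AP-1 and immediate early genes (median 0.272, camera adjusted p = 8.6e-05, adjusted p = 0.0373 with an estimated correlation) had 6 of 23 higher and 1 lower, or 7 and 1 when adjusted over the list alone. NF-kB target and cytokine genes were lower (median -0.286, camera adjusted p = 1.89e-04, adjusted p = 0.00708 with an estimated correlation), with 3 of 8 lower, or 4 when adjusted over the list alone. They included TNFAIP3 (-1.02 ± 0.13, adjusted p = 2.42e-05), and with no filter the list's adjusted p was 0.24. Heat shock genes were higher (median 0.13, camera adjusted p = 8.24e-04, adjusted p = 0.0264 with an estimated correlation), with 1 of 12, BAG3, past the threshold (0.65 ± 0.09, adjusted p = 1.05e-04) and 4 when adjusted over the list alone. Histone genes were higher (median 0.278, camera adjusted p = 0.00272, adjusted p = 0.328 with an estimated correlation), with 2 of 15 higher, and 2 when adjusted over the list alone, and an adjusted p of 0.291 with the filter at 7. Limma called 238 genes in this comparison, of which 133 were lower at the higher dose, and after the shift by reference genes 42 higher and 212 lower. NPTXR missed the threshold with only the groups compared (adjusted p = 0.0628).

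At 75 nM and 24 h, IL7R, the interleukin-7 receptor chain, fell from 7.54 ± 0.46 (SD, n = 4) to 6.15 ± 0.35 (SD, n = 5), a change of -1.39 ± 0.28 (limma adjusted p = 0.0161). Other large falls were those of RHAG, an ammonium transporter (-1.77 ± 0.38, adjusted p = 0.0213), the histone gene H2BC14 (-1.76 ± 0.42, adjusted p = 0.0378) and MAMDC2 (-1.52 ± 0.26, adjusted p = 0.00762). The largest rises were those of HEXD, a hexosaminidase (1.16 ± 0.21, adjusted p = 0.0084), and C20orf96 (1.12 ± 0.23, adjusted p = 0.0162). The long non-coding RNA gene SLC9A3-OT1 (0.98 ± 0.18, adjusted p = 0.0084) and PBXIP1, which binds PBX homeobox factors (0.96 ± 0.20, adjusted p = 0.0158) rose too. MYC stood at -0.01 ± 0.13 (adjusted p = 0.985), HEXIM1 at 0.32 ± 0.13 (adjusted p = 0.201) and FOSL1 at -0.48 ± 0.15 (adjusted p = 0.116), none of them past the test. Neither were BRD2 (0.18, adjusted p = 0.258), BRD3 (0.30, adjusted p = 0.306) and CCND1 (0.21, adjusted p = 0.408).

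As groups at 75 nM and 24 h, ribosome biogenesis and MYC target genes were lower (median -0.203, camera adjusted p = 3.24e-07, adjusted p = 0.0307 with an estimated correlation), with 2 of 31 fallen, and 2 when adjusted over the list alone. NF-kB target and cytokine genes were lower (median -0.324, camera adjusted p = 0.00199, adjusted p = 0.0307 with an estimated correlation), with 1 of 8 fallen, or 2 when adjusted over the list alone, and an adjusted p of 0.0776 with no filter. DNA replication genes (median -0.178, camera adjusted p = 1.42e-05) had an adjusted p = 0.541 with an estimated correlation. Limma called 0 of their 34 members over all genes, 2 when adjusted over the list alone and 10 at an unadjusted p below 0.05. Mitosis genes (median -0.261, camera adjusted p = 5.54e-05, adjusted p = 0.541 with an estimated correlation) had 0 of 30 called by limma over all genes, 0 when adjusted over the list alone and 6 at an unadjusted p below 0.05. Amino acid and unfolded protein stress genes (median -0.165, camera adjusted p = 0.00299, adjusted p = 0.226 with an estimated correlation) had 0 of 25 called by limma, 0 when adjusted over the list alone and 9 at an unadjusted p below 0.05. DUSP6, a phosphatase of the kinase ERK, rose by 0.54 ± 0.10 (adjusted p = 0.00954).

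Limma called 81 genes at 75 nM and 24 h, 37 higher and 44 lower, with 2 risen and 13 fallen at least 2-fold, and after the shift by reference genes 13 higher and 72 lower. The count was 52, 50 and 43 without DMSO 24 h replicate 1, 2 and 3, and 45 and 41 without 75 nM replicate 2 and 3. It was 18 with no filter, 52 with only the groups compared, 129 after repeated quantile normalization (69 higher and 60 lower) and 187 with array weights. The replicate block gave 234 (102 higher and 132 lower), with 3 of 4 pairs correlating above 0.1. The calls of several genes depended on a single array. RHAG missed the threshold without DMSO replicate 1 (adjusted p = 0.0785) or 3 (0.0711) or 75 nM replicate 2 (0.0543) or 3 (0.0551). IL7R missed it without DMSO replicate 1 (0.062) or 2 (0.0631), C20orf96 without DMSO replicate 1 (0.0697) or 3 (0.0733), and PBXIP1 without DMSO replicate 1 (0.0613) or 3 (0.0605). H2BC14 missed it without any DMSO replicate (0.062, 0.113, 0.0733 and 0.0741 for replicates 1 to 4) and without 75 nM replicate 1 (0.0519), 2 (0.102), 3 (0.0614) or 4 (0.0649).

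At 468 nM and 24 h, most measured genes of the cell cycle lists fell. All 34 measured DNA replication genes fell (median -1.22, camera adjusted p = 2.23e-22, adjusted p = 0.0473 with an estimated correlation), and 34 when adjusted over the list alone. They included the origin and helicase factors MCM10 (-1.62 ± 0.11, limma adjusted p = 3.68e-11), CDC6 (-1.60 ± 0.11, adjusted p = 5.15e-11) and MCM5 (-1.54 ± 0.12, adjusted p = 1.5e-10) and thymidylate synthase, TYMS (-1.61 ± 0.13, adjusted p = 3.06e-10). All 30 mitosis genes fell, and 30 when adjusted over the list alone, with a median of -1.45 (camera adjusted p = 1.08e-19, but adjusted p = 0.0621 with an estimated correlation). Among them were the mitotic kinase PLK1 (-1.72 ± 0.12, adjusted p = 5.15e-11), the spindle factor TPX2 (-1.29 ± 0.11, adjusted p = 1.17e-09) and the kinesins KIF20A (-1.72 ± 0.16, adjusted p = 4.05e-09) and KIF11 (-1.58 ± 0.15, adjusted p = 5.78e-09). G1/S regulators were lower (median -0.787, camera adjusted p = 1.09e-06, adjusted p = 0.00171 with an estimated correlation), with 13 of 16 fallen and 1, RB1, the brake on S phase entry, risen, and the same counts when adjusted over the list alone. E2F8, an E2F family repressor, fell from 7.45 ± 0.20 (SD, n = 4) to 4.37 ± 0.29 (SD, n = 5), a change of -3.08 ± 0.16 (limma adjusted p = 4.58e-13). The phosphatase gene CDC25A (-1.58 ± 0.11, adjusted p = 5.15e-11) and cyclin A2, CCNA2 (-1.80 ± 0.14, adjusted p = 3.31e-10), fell as well.

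The largest single changes at 468 nM and 24 h lay outside those lists or in the histone genes. H2BC14 fell from 8.87 ± 0.33 (SD, n = 4) to 3.96 ± 1.35 (SD, n = 5), a change of -4.92 ± 0.42 (limma adjusted p = 1.15e-09). Further large falls were those of IL7R, from 7.54 ± 0.46 to 2.82 ± 0.33 (-4.72 ± 0.28, adjusted p = 5.83e-12), the interleukin-33 receptor IL1RL1 (-4.24 ± 0.50, adjusted p = 1.94e-07) and IL6 (-3.71 ± 0.59, adjusted p = 1.23e-05). The lectin gene CLEC2B (-3.95 ± 0.23, adjusted p = 3.51e-12), GIPC3 (-3.48 ± 0.26, adjusted p = 1.5e-10), FAM216B (-3.47 ± 0.24, adjusted p = 5.1e-11) and the myelin protein gene MOG (-3.26 ± 0.38, adjusted p = 1.44e-07) were also among the largest falls. The rises were led by H2BC18 (3.89 ± 0.31, adjusted p = 4.3e-10), from 2.0 ± 0.15, near the bottom of the scale, to 5.89 ± 0.35. Means this low, such as those of H2BC18 in DMSO and of IL7R, IL6 and CLEC2B at 468 nM, lie near the median of all probe sets or below it. The sizes of these changes are therefore uncertain. Next came TXNIP, which binds thioredoxin and restrains glucose uptake (2.77 ± 0.18, adjusted p = 1.14e-11), with its relative ARRDC4 (2.11 ± 0.15, adjusted p = 4.81e-11). Further rises were those of YPEL3, a growth-suppressive zinc-binding protein (2.24 ± 0.35, adjusted p = 1.01e-05), and the sestrin SESN3, a restraint on mTORC1 (2.17 ± 0.16, adjusted p = 1.25e-10). NPTXR (2.16 ± 0.28, adjusted p = 8.27e-07), ZC3H6 (2.1 ± 0.20, adjusted p = 7.89e-09) and KLHL24 (1.97 ± 0.20, adjusted p = 2.28e-08) rose as well.

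HEXIM1 remained raised at 468 nM and 24 h (1.30 ± 0.13, limma adjusted p = 8.76e-09), and MYC was lower by a smaller amount, from 8.87 ± 0.12 (SD, n = 4) to 8.33 ± 0.33 (SD, n = 5; -0.54 ± 0.13, adjusted p = 0.00185). FOSL1, an AP-1 subunit, fell by 1.76 ± 0.15 on the log2 scale (adjusted p = 1.42e-09). BRD2 (0.33 ± 0.08, adjusted p = 0.00121) and BRD3 (0.49 ± 0.14, adjusted p = 0.00774) rose, and CCND1 stood at -0.01 (adjusted p = 0.964). Of 9 measured BET inhibitor markers 3 rose, including H2BC21 (1.66 ± 0.21, adjusted p = 6.75e-07), and 4 fell (same over the list alone). The list mixes directions, so camera's test of a shared one (adjusted p = 0.874) decides nothing. The 15 listed histone genes had 5 risen and 5 fallen, or 5 and 6 when adjusted over the list alone (camera adjusted p = 0.874). Of 18 genes of BET proteins and the P-TEFb complex 8 rose and 1 fell, or 8 and 2 when adjusted over the list alone (camera adjusted p = 0.163). There were rises of the elongation factors ELL2 (0.81 ± 0.08, adjusted p = 2.31e-08) and MLLT3 (1.0 ± 0.13, adjusted p = 4.93e-07) and a fall of JMJD6 (-1.13 ± 0.17, adjusted p = 5.5e-06). Of 7 MYC family genes 2 rose and 1 fell, the same when adjusted over the list alone (camera adjusted p = 0.723), MXD1 by 1.04 ± 0.19 (adjusted p = 7.59e-05).

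Growth-related lists were lower at 468 nM and 24 h. Of 31 ribosome biogenesis and MYC target genes 28 fell, and 28 when adjusted over the list alone (median -0.676, camera adjusted p = 6.56e-12, adjusted p = 0.00171 with an estimated correlation), including the purine synthesis enzyme PAICS (-0.90 ± 0.08, limma adjusted p = 1.17e-09) and the nucleolar proteins DDX21 (-1.11 ± 0.10, adjusted p = 1.73e-09) and NOP58 (-0.70 ± 0.08, adjusted p = 4.05e-08). Of 25 amino acid and unfolded protein stress genes 16 fell, and 16 when adjusted over the list alone (median -0.528, camera adjusted p = 9.66e-05, but adjusted p = 0.0516 with an estimated correlation), among them the serine synthesis enzyme PSAT1 (-0.99 ± 0.10, adjusted p = 9.24e-09) and XBP1, a transcription factor of the unfolded protein response (-1.12 ± 0.12, adjusted p = 8.3e-08). Heat shock genes were lower too (median -0.341, camera adjusted p = 0.00681, but adjusted p = 0.0516 with an estimated correlation), 7 of 12 having fallen, and 7 when adjusted over the list alone, with HSPB1 at -0.77 ± 0.08 (adjusted p = 5.79e-08). Of 14 glycolysis and hypoxia genes 4 rose and 7 fell, or 5 and 7 when adjusted over the list alone (camera adjusted p = 0.723), and hexokinase 2, HK2, fell by 1.37 ± 0.14 (adjusted p = 2.93e-08).

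Other lists at 468 nM and 24 h differed in direction. NF-kB target and cytokine genes were lower (median -0.788, camera adjusted p = 0.00162, adjusted p = 0.0247 with an estimated correlation), with 6 of 8 fallen, and 6 when adjusted over the list alone, TNFAIP3 by 1.28 ± 0.13 (limma adjusted p = 2.44e-08). CDK inhibitors and p53 target genes were higher (median 0.388, camera adjusted p = 0.029, but adjusted p = 0.0516 with an estimated correlation), with 8 of 15 risen and 2 fallen, the same when adjusted over the list alone. GADD45A rose (1.29 ± 0.16, adjusted p = 5.12e-07) while AEN, a p53-induced nuclease, fell (-1.78 ± 0.14, adjusted p = 3.66e-10). Lysosome and autophagy genes were higher (median 0.359, camera adjusted p = 0.00162, but adjusted p = 0.203 with an estimated correlation), with 13 of 27 risen and 2 fallen, or 15 and 2 when adjusted over the list alone. Among them were the membrane protein LAMP2 (0.66 ± 0.08, adjusted p = 1.54e-07) and prosaposin, PSAP (0.62 ± 0.11, adjusted p = 3.91e-05). AP-1 and immediate early genes had 8 of 23 risen and 4 fallen, the same when adjusted over the list alone (camera adjusted p = 0.264). Of 17 MAPK feedback genes 3 rose and 4 fell, the same when adjusted over the list alone (camera adjusted p = 0.948), with DUSP6 risen (1.32 ± 0.10, adjusted p = 2.54e-10) and DUSP7 fallen (-1.35 ± 0.15, adjusted p = 1.24e-07).

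Lists of cell identity and surroundings passed camera at neither time for 468 nM against DMSO, and the values here are those at 24 h. Of 8 melanocyte lineage genes 4 rose and 2 fell (camera adjusted p = 0.697), SOX10 by 0.58 ± 0.13 (limma adjusted p = 8.51e-04), while the endothelin receptor EDNRB fell (-1.21 ± 0.29, adjusted p = 0.00138). Of 16 undifferentiated melanoma state genes 3 rose and 4 fell (camera adjusted p = 0.874), including SNAI1 (-1.12 ± 0.16, adjusted p = 3.99e-06) and the cadherin CDH2 (0.84 ± 0.14, adjusted p = 2.17e-05). Of 16 BCL2 family genes 4 rose and 2 fell (camera adjusted p = 0.874, with a median of -0.0811 and a mean of 0.0186), BCL2L11 by 1.22 ± 0.20 (adjusted p = 2.32e-05). Of 16 interferon-stimulated genes 4 rose and 5 fell (camera adjusted p = 0.948). These counts were the same when adjusted over the list alone. Of 27 extracellular matrix and adhesion genes 6 rose and 3 fell, or 5 and 3 when adjusted over the list alone (camera adjusted p = 0.874, with a median of 0.0174 and a mean of -0.0339), with the integrin ITGA4 at -1.29 ± 0.14 (adjusted p = 3.11e-08). Of 17 cholesterol synthesis genes 2 rose and 4 fell, or 2 and 3 when adjusted over the list alone (camera adjusted p = 0.874, with a median of -0.0193 and a mean of 0.0833), TM7SF2 by 1.81 ± 0.22 (adjusted p = 2.79e-07). Of 17 receptor tyrosine kinases and growth factors 3 rose and 6 fell, or 3 and 7 when adjusted over the list alone (camera adjusted p = 0.874). Among the 9 reference genes 3 rose and 4 fell, the same when adjusted over the list alone (camera adjusted p = 0.949), and under each of 3 other scalings as well.

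**Figure D3:**
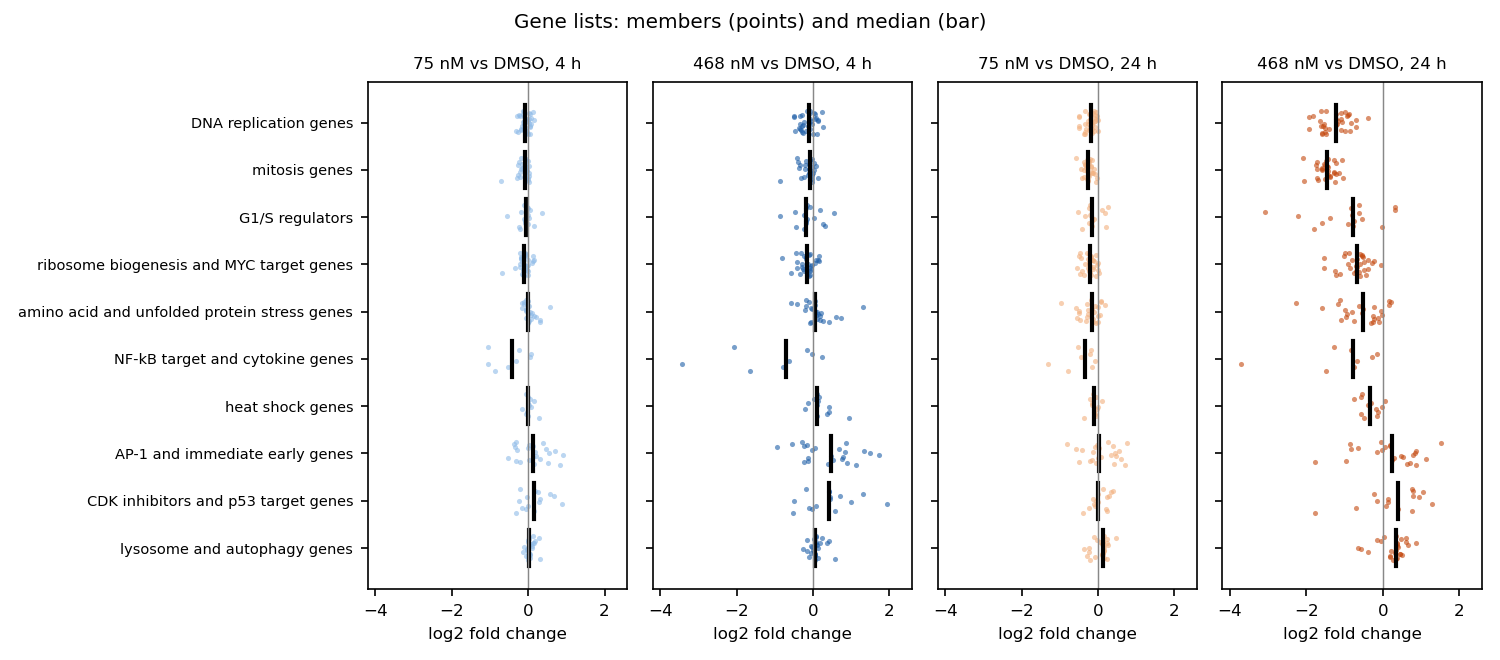
Each panel is a comparison with DMSO, each line 1 of 10 gene lists and each point a measured member, with the log2 fold change on the x axis and a bar at the list's median. At 468 nM and 24 h the DNA replication genes centre on -1.22 and the mitosis genes on -1.45, while at 4 h the NF-kB target genes lie lowest with a median of -0.708.

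**Figure D4:**
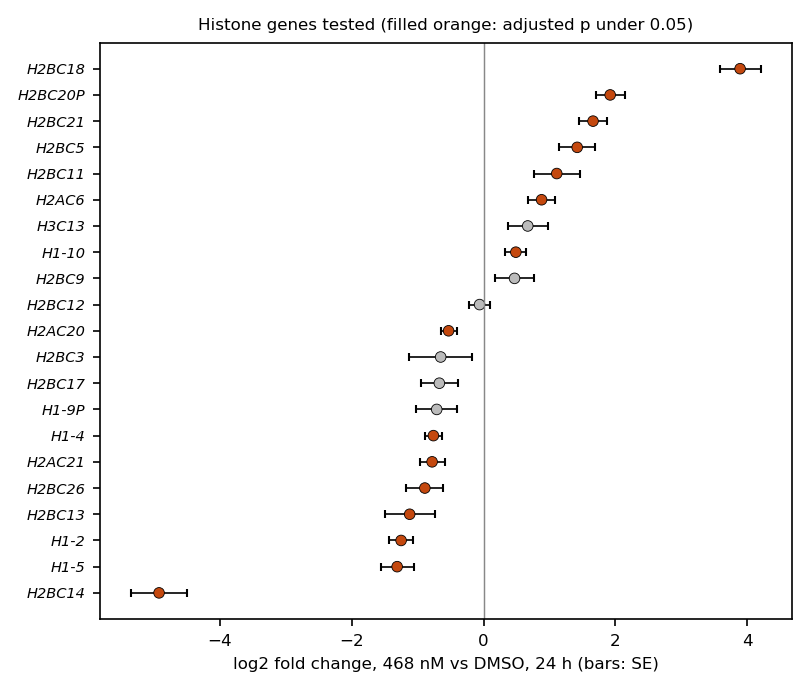
Log2 fold changes (x axis) of the 21 tested histone genes at 468 nM against DMSO at 24 h, with bars for the SE, orange points for an adjusted p below 0.05 and grey points otherwise. Of these genes 7 rose and 8 fell, with 9 fallen after centring on the median or the shift by reference genes and 7 after repeated quantile normalization.

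Limma called 4231 genes at 468 nM and 24 h, 1896 higher and 2335 lower, which was 45.6% of those tested, with 258 risen and 625 fallen at least 2-fold. After repeated quantile normalization 2156 were higher and 2065 lower, and after the shift by reference genes 1529 and 2220, so which direction held more genes depended on the scaling. Without 468 nM replicate 2, which lay apart on the principal components, 4057 were called. With the mean of all its probe sets BRD2 had an adjusted p = 0.0817, and with only the groups compared BRD3 had an adjusted p = 0.0548. H2BC18 is represented by 3 probe sets whose changes were 3.89, 3.77 and 1.21, and 1 of the 8 probe sets of MOG, with a mean of 1.32, stood at -0.01.

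Between doses at 24 h, IL7R was lower at 468 nM than at 75 nM by a difference of -3.33 ± 0.27 (limma adjusted p = 1.69e-09), and CLEC2B by one of -3.18 ± 0.21 (adjusted p = 1.5e-10). H2BC14 was lower by a difference of -3.16 ± 0.40 (adjusted p = 1.18e-06) and IL1RL1 of -3.15 ± 0.47 (adjusted p = 1.39e-05). H2BC18 (2.92 ± 0.30, adjusted p = 5.1e-08), TXNIP (2.1 ± 0.17, adjusted p = 1.38e-09), ARRDC4 (1.82 ± 0.14, adjusted p = 6.76e-10) and SAT1, the polyamine catabolic enzyme (1.64 ± 0.26, adjusted p = 3.48e-05), had the largest positive differences. MYC (-0.53 ± 0.13, adjusted p = 0.00225), FOSL1 (-1.28 ± 0.14, adjusted p = 2.52e-07) and HEXIM1 (0.97 ± 0.12, adjusted p = 7.7e-07) also differed. Limma called 2860 genes, 1246 higher and 1614 lower at the higher dose. After the shift by reference genes 1274 were higher and 1153 lower, and after repeated quantile normalization 1398 and 1402.

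The same growth and cell cycle lists separated the doses at 24 h. Lower at 468 nM were 33 of 34 DNA replication genes (34 when adjusted over the list alone, median -1.05, camera adjusted p = 3.07e-29, adjusted p = 0.0233 with an estimated correlation). So were 30 of 30 mitosis genes (30 when adjusted over the list alone, median -1.21, camera adjusted p = 3.51e-25, adjusted p = 0.0454 with an estimated correlation). The same held for 13 of 16 G1/S regulators (13 when adjusted over the list alone, median -0.612, camera adjusted p = 2.33e-09, adjusted p = 2.11e-04 with an estimated correlation). It also held for 24 of 31 ribosome biogenesis and MYC target genes (26 when adjusted over the list alone, median -0.498, camera adjusted p = 2.82e-11, adjusted p = 0.00235 with an estimated correlation). E2F8 differed by -2.56 ± 0.15 (limma adjusted p = 9.68e-12), the chromatin factor UHRF1 by -1.38 ± 0.11 (adjusted p = 1.42e-09) and the kinase AURKA by -1.81 ± 0.19 (adjusted p = 6.76e-08). NF-kB target genes (median -0.634, camera adjusted p = 0.0115, adjusted p = 0.0454 with an estimated correlation) were lower in 6 of 8, and 6 when adjusted over the list alone. CDK inhibitors and p53 target genes (median 0.274, camera adjusted p = 0.02, adjusted p = 0.0454 with an estimated correlation) were higher in 7 of 15 and lower in 2, or 8 and 2 when adjusted over the list alone. A further 3 lists passed camera only with the preset correlation. Amino acid and unfolded protein stress genes (median -0.267, adjusted p = 2.88e-04, adjusted p = 0.0568 with an estimated correlation) were lower in 15 of 25, or 15 with 2 higher when adjusted over the list alone. Lysosome and autophagy genes (median 0.229, adjusted p = 0.00239, adjusted p = 0.228 with an estimated correlation) were higher in 9 of 27 and lower in 1, the same when adjusted over the list alone. Heat shock genes (median -0.151, adjusted p = 0.0115, adjusted p = 0.0614 with an estimated correlation) were lower in 5 of 12, and 5 when adjusted over the list alone.

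The genes called at 75 nM were set against those called at 468 nM, with the caution that both comparisons share the DMSO arrays. At 4 h all 63 genes changed at 75 nM also changed in the same direction at 468 nM, where independent lists would share 3.45. Simulated unchanged groups shared 0, but they called fewer than 1 gene on average and so set no chance level for the overlap. With the DMSO arrays split so that the doses shared none, 15 to 23 genes were shared, from lists of 15 to 25 at the lower dose. The covariance of the fold changes was 0.0607, and 0.0197 in the simulated groups. At 24 h 80 of 81 genes were shared in direction, against 18.6 for independent lists, and 0 to 37 with the DMSO arrays split, and the covariance was 0.123 against 0.0193. Between 4 h and 24 h, which share no arrays, 558 genes changed in the same direction at 468 nM and 60 in opposite directions, against 237 expected in the same direction from independent lists, and at 75 nM 6 genes were shared against 0.275.

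Whether the effect of a dose differed between times was tested as an interaction. At 468 nM the effect on cell cycle genes was more negative at 24 h than at 4 h. E2F8 had an interaction of -2.61 ± 0.22 (limma adjusted p = 1.91e-08), CDC6 of -1.71 ± 0.16 (adjusted p = 4.92e-08) and PLK1 of -1.33 ± 0.17 (adjusted p = 5.2e-06). The largest negative values were those of CLEC2B (-3.73 ± 0.32, adjusted p = 1.91e-08), H2BC14 (-3.71 ± 0.59, adjusted p = 7.25e-05), GIPC3 (-3.54 ± 0.37, adjusted p = 2.47e-07) and FAM216B (-3.52 ± 0.34, adjusted p = 9.47e-08). The largest positive ones were those of the long non-coding RNA gene LPP-AS2 (2.63 ± 0.35, adjusted p = 1.04e-05) and H2BC18 (2.58 ± 0.44, adjusted p = 1.47e-04). YPEL3 (2.26 ± 0.49, adjusted p = 0.00159) and TBC1D2B, a regulator of Rab GTPases (2.17 ± 0.20, adjusted p = 3.66e-08), followed. Opposite movements gave interactions for SOX10 (1.31 ± 0.19, adjusted p = 2.26e-05), which fell at 4 h and rose at 24 h, and for BAG3 (-1.42 ± 0.14, adjusted p = 9.47e-08), which rose at 4 h and fell at 24 h. FOSL1 had an interaction of -1.53 ± 0.22 (adjusted p = 1.81e-05).

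MYC fell less at 24 h than at 4 h at 468 nM (interaction 0.53 ± 0.19, limma adjusted p = 0.0428), and this call was lost without any of 11 arrays. Without 468 nM, 4 h replicate 1 or 5 its adjusted p was 0.0744 or 0.0804, and without 468 nM, 24 h replicate 1, 3 or 5 it was 0.0826, 0.0773 or 0.0739. Without DMSO 4 h replicate 1, 2 or 3 it was 0.0738, 0.0818 or 0.0525, and without DMSO 24 h replicate 2, 3 or 4 it was 0.0548, 0.0862 or 0.0669. With each array centred on its median it was 0.0526, and after repeated quantile normalization 0.0501.

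Limma called 2184 interactions at 468 nM, 1005 positive and 1179 negative, and after the shift by reference genes 1112 positive and 749 negative. DNA replication genes had negative interactions in 31 of 34 (34 when adjusted over the list alone, median -1.17, camera adjusted p = 4.74e-25, adjusted p = 0.0254 with an estimated correlation). Mitosis genes had them in 30 of 30 (30 when adjusted over the list alone, median -1.33, camera adjusted p = 2.54e-22, but adjusted p = 0.0573 with an estimated correlation). The same held for 12 of 16 G1/S regulators (median -0.873, camera adjusted p = 1.86e-07, adjusted p = 0.00113 with an estimated correlation), of which 13 were negative and 1 positive when adjusted over the list alone. It held for 19 of 31 ribosome biogenesis and MYC target genes (24 when adjusted over the list alone, median -0.509, camera adjusted p = 8.26e-10, adjusted p = 0.00478 with an estimated correlation). It held as well for 14 of 25 amino acid and unfolded protein stress genes (17 when adjusted over the list alone, median -0.752, camera adjusted p = 8.17e-08, adjusted p = 0.00803 with an estimated correlation), and for 7 of 12 heat shock genes (8 when adjusted over the list alone, median -0.508, camera adjusted p = 1.44e-05, adjusted p = 0.00478 with an estimated correlation). Histone genes (5 of 15 negative, and 5 when adjusted over the list alone, median -0.62, camera adjusted p = 0.0205) had an adjusted p = 0.437 with an estimated correlation and 0.131 with the filter at 7. Lysosome and autophagy genes (3 of 27 positive and 1 negative, or 2 and 1 when adjusted over the list alone, median 0.302, camera adjusted p = 0.0258) also had an adjusted p = 0.437 with an estimated correlation.

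At 75 nM limma called 3 interactions, all positive, against 635 at an unadjusted p below 0.05. They were TBC1D2B (1.13 ± 0.20, adjusted p = 0.0187), the zinc finger and homeobox gene ZHX2 (0.95 ± 0.15, adjusted p = 0.00968) and SH3RF2 (0.72 ± 0.13, adjusted p = 0.0187). The number called was 1 without DMSO 4 h replicate 1 or 2 or without DMSO 24 h replicate 3, 5 without 75 nM, 4 h replicate 5, and 0 with no filter or after the shift by reference genes. It was 7 with array weights (5 positive and 2 negative) and 11 with the replicate block (7 positive and 4 negative). TBC1D2B missed the threshold without DMSO 4 h replicate 1 (0.0823) or 2 (0.0822) or DMSO 24 h replicate 3 (0.069) or 4 (0.0634). SH3RF2 missed it without the same 4 h replicates (0.0823 and 0.0822), DMSO 24 h replicate 2 (0.064) or 3 (0.0777) or 75 nM, 24 h replicate 5 (0.0547). ZHX2 missed it with no filter (0.115) or after the shift by reference genes (0.183). Ribosome biogenesis and MYC target genes (median -0.116, camera adjusted p = 0.00406, adjusted p = 0.268 with an estimated correlation) had more negative effects at 24 h as a group. So had DNA replication genes (median -0.162, camera adjusted p = 0.00406, adjusted p = 0.88 with an estimated correlation) and amino acid and unfolded protein stress genes (median -0.21, camera adjusted p = 1.55e-04, adjusted p = 0.192 with an estimated correlation). Limma called 0 members of each over all genes and 0 when adjusted over the list alone, with 4 at an unadjusted p below 0.05 in each list.

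The DMSO arrays gave the background change with time in culture. TNFRSF12A, the receptor of the cytokine TWEAK, fell from 9.90 at 4 h to 7.66 at 24 h (-2.24 ± 0.21, limma adjusted p = 6.17e-07, n = 4 and 4). Among genes without overlap between the groups it was followed by the transcription factor genes NFATC2 (-1.82 ± 0.24, adjusted p = 6.98e-05) and FOXF1 (-1.54 ± 0.24, adjusted p = 4.85e-04) and by GPR137C (-1.53 ± 0.23, adjusted p = 4.85e-04). The rises were led by GDPD1 (1.89 ± 0.31, adjusted p = 9.54e-04) and RFTN2 (1.61 ± 0.31, adjusted p = 0.0035). The small nucleolar RNA gene SNORD17 (1.52 ± 0.31, adjusted p = 0.00577) and the stress-induced mTORC1 inhibitor DDIT4 (1.46 ± 0.20, adjusted p = 8.87e-05) rose too. G1/S regulators were lower at 24 h (median -0.287, camera adjusted p = 1.4e-04, adjusted p = 0.0136 with an estimated correlation), with 4 of 16 fallen, or 7 when adjusted over the list alone, including CDC25A (-0.67 ± 0.12, adjusted p = 0.00171) and E2F8 (-0.77 ± 0.17, adjusted p = 0.0091). UHRF1 fell (-0.81 ± 0.12, adjusted p = 4.3e-04) and HERPUD1, a gene of the unfolded protein response, rose (0.98 ± 0.12, adjusted p = 3.89e-05).

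A further 6 lists passed camera over time in DMSO but not with an estimated correlation. DNA replication genes (median -0.274, camera adjusted p = 2.98e-08, adjusted p = 0.44 with an estimated correlation) had 2 of 34 fallen, or 12 when adjusted over the list alone. Ribosome biogenesis and MYC target genes (median -0.149, camera adjusted p = 9.93e-04, adjusted p = 0.178 with an estimated correlation) had 3 of 31 fallen, or 5 when adjusted over the list alone. Mitosis genes (median -0.183, camera adjusted p = 0.0163, adjusted p = 0.604 with an estimated correlation) had 0 of 30 called by limma, 0 when adjusted over the list alone and 6 at an unadjusted p below 0.05. Undifferentiated melanoma state genes (median -0.205, camera adjusted p = 0.0178, adjusted p = 0.44 with an estimated correlation) had 3 of 16 fallen, or 4 fallen and 1 risen when adjusted over the list alone. CCN1 was among the fallen (-0.92 ± 0.18, limma adjusted p = 0.00394). Cholesterol synthesis genes were higher (median 0.312, camera adjusted p = 0.00332, adjusted p = 0.604 with an estimated correlation) with 0 of 17 called by limma, 0 when adjusted over the list alone and 3 at an unadjusted p below 0.05. Heat shock genes were higher (median 0.158, camera adjusted p = 0.00465, adjusted p = 0.111 with an estimated correlation), with BAG3 the 1 of 12 that rose (0.62 ± 0.10, adjusted p = 9.54e-04), and 4 when adjusted over the list alone. Limma called 486 genes, 244 higher and 242 lower, and after the shift by reference genes 757 higher and 76 lower. The count was 201, 247 and 201 without DMSO 4 h replicate 1, 2 and 3, and 217 without DMSO 24 h replicate 2 or 4. It was 103 with no filter, 113 with only the groups compared and 830 with array weights. The replicate block gave 908 (490 higher and 418 lower), although its sets did not pair these arrays.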

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

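The test for a single 75 nM array out of line was chosen only after the result it measures was seen. So was the block of code sets 2 and 4. The expectations for the other explanations were set before their tests were run. The patterns in dose, histone genes and neighbouring genes were themselves found in these data, as were the histone genes that fell or rose.

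The 3 genes whose effect of 75 nM differed between times were TBC1D2B (1.13), ZHX2 (0.95) and SH3RF2 (0.72), all more positive at 24 h on the log2 scale. Amino acid and unfolded protein stress genes (median -0.21), DNA replication genes (-0.162) and ribosome biogenesis and MYC target genes (-0.116) had more negative effects of 75 nM at 24 h than at 4 h. None of these 3 lists passed with an estimated correlation (adjusted p = 0.192, 0.88 and 0.268), and limma called 0 members of each.

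At 468 nM the effect differed between times for 2184 genes. The cell cycle accounted for the most negative lists, with medians of -1.33 for mitosis genes, -1.17 for DNA replication genes and -0.873 for G1/S regulators. Amino acid and unfolded protein stress genes (-0.752), histone genes (-0.62), ribosome biogenesis and MYC target genes (-0.509) and heat shock genes (-0.508) were also more negative at 24 h, and lysosome and autophagy genes more positive (0.302). With an estimated correlation the lists of mitosis (adjusted p = 0.0573), histone (0.437) and lysosome and autophagy genes (0.437) did not pass. Among single genes CLEC2B (-3.73), H2BC14 (-3.71), GIPC3 (-3.54), FAM216B (-3.52) and FOSL1 (-1.53) had more negative effects at 24 h. LPP-AS2 (2.63), H2BC18 (2.58), YPEL3 (2.26), TBC1D2B (2.17) and MYC (0.53) had more positive ones. The call of MYC (limma adjusted p = 0.0428) was lost without any 1 of 11 arrays, with only the groups compared (0.0799), with no filter (0.132), after centring on the median (0.0526) and after repeated quantile normalization (0.0501).

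In some groups 1 array lay far from the others of its group, where chance flags about 1 in 20 groups and 10 of 144 groups were found. HEXIM1 was at 7.72 in 75 nM, 4 h replicate 3. FGF18 was at 4.19 in 468 nM, 4 h replicate 1, and CCND1 at 8.92 in 468 nM, 4 h replicate 2. MAMDC2 was at 3.0 in 75 nM, 24 h replicate 2, and IL6 at 3.32 in 468 nM, 24 h replicate 1. The array 468 nM, 24 h replicate 2 stood apart for IL7R (3.39), MOG (2.53), the median log2 value (2.49) and the second principal component (16.12). The array 75 nM, 24 h replicate 4 stood at 5.29 on the first principal component. No explanation of these single arrays was tested.

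Signal also appeared in probe sets that the comparisons did not use. Of 4177 probe sets with no listed symbol, 84 changed at 468 nM and 4 h and 733 at 468 nM and 24 h. Of 781 probe sets with several symbols, 64 and 354 changed at these times.

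Far fewer genes passed the threshold at 75 nM than at 468 nM after 24 h, 81 against 4231. In the shared fit each gene has the same standard error at both doses (median 0.149). A wider spread of the 75 nM arrays therefore could not cause this gap. With only the groups compared, where each comparison has its own spread, 52 and 3284 genes were called. A wider spread there is argued against by the ratio of median SDs within the groups, 0.72, which was 0.658 to 0.832 without 1 array. A single 75 nM array out of line is argued against by the counts without each of these arrays, the highest of which was 87. With a shared standard error, fewer calls follow from smaller fold changes by construction. What was left to measure is whether the same genes moved. With DMSO arrays split between doses, the slope of 75 nM on 468 nM fold changes was 0.258 over genes called at 468 nM. Of these, 83.1% had the same direction. The dose itself, which the design sets, stays an open explanation of why the changes were smaller.

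Histone genes changed in opposite directions at 468 nM after 24 h. Of 11 tested H2B genes, not counting H2BC20P, which rose, 3 fell and 4 rose, and signal shared between near-identical genes stays open, as it was not tested. Over the 28 arrays, deviations from group means of the histone genes that fell correlated with those of the DNA replication genes (Pearson r = 0.775, permutation p = 1e-05, the smallest these permutations can give, and adjusted p = 2e-05 over both relations). Spearman's rho was 0.611 (permutation p = 0.00075), and r was 0.466 without the 2 farthest arrays and 0.81 with the code sets removed. For the histone genes that rose no such relation was seen (r = -0.119, permutation p = 0.533, adjusted p = 0.533; rho = -0.112, permutation p = 0.569; r = -0.208 without the 2 farthest arrays and -0.315 with the code sets removed), but following genes that fell would not give a rise, so these values decide nothing for the rises. A drop in S phase cells may lie behind the falls, stays open for the rises, and was not itself measured.

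Genes that fell at 468 nM after 4 h lay beside each other more often than chance, with 59 neighbouring pairs against a mean of 44.5 in 10000 random placements (permutation p = 0.0152). Pairs that include IL6, IL6-AS1 or STEAP1B-AS1, among the largest falls, were left out of all counts of pairs here. Signal shared by overlapping genes is argued against as the whole cause, since 52 pairs that do not overlap fell together against a mean of 41.1 (permutation p = 0.047), near the threshold. The genes that rose had 16 neighbouring pairs against 14.5 (permutation p = 0.383). At 24 h both the falls (633 pairs against 585, permutation p = 0.0055) and the rises (421 against 386, permutation p = 0.0163) lay together more often than chance. Shared regulation of neighbouring genes could lie behind the pattern, and no biological explanation was tested.

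Other splits of the same arrays into groups of the same sizes were tried, 100 for each comparison and 35 for DMSO over time. At 24 h only 1 split, the real one, gave as many genes for 468 nM against DMSO (4231, highest other 3479). The same held for 468 nM against 75 nM (2860, highest other 1091) and 75 nM against DMSO (81, highest other 2). It also held for DMSO over time (486, highest other 1), where the code sets did not pair the arrays. Arrays correlated best with their own code set in 4 of 4 pairs at 24 h (4 at 4 h) for 75 nM with DMSO. It was 3 of 4 (2) for 468 nM and 5 of 5 (5) between doses. These splits ignore such pairing, so they do not exclude chance at 24 h. Since the samples of a group may be technical replicates, no split excludes chance between cultures. Only 1 split also gave as many for 468 nM against DMSO at 4 h (1013, highest other 470) and between doses at 4 h (238, highest other 36). These splits ignore the pairing of the 4 h arrays. For the interaction at 468 nM no shuffle gave as many as the real 2184 (highest 121), but the shuffles ignore that pairing too. For the interaction at 75 nM 3 splits gave as many as the real 3 genes, and the highest other gave 7. For 75 nM at 4 h 2 splits gave as many as the real 63, and the highest other, 111, parted the arrays of code sets 2 and 4 from the rest. Both shares are under 0.05, but other splits exceeded the real counts. The split with 111 points to a structure of the samples, and the count was 82 with the replicate block and 79 with code sets 2 and 4 as a block. The 16 splits that part as many pairs in each dose comparison, at 4 h or 24 h, are too few for a share under 0.05. The highest other among them at 4 h was 3 for 75 nM (63), 426 for 468 nM (1013) and 1 between doses (238). At 24 h it was 1 for 75 nM (81), 2985 for 468 nM (4231) and 503 between doses (2860).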

How the results depend on the processing

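Only the block of code sets 2 and 4 was tried after the results were seen, and the other tests here were planned. No named gene reversed under any alternative run.

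With array weights 187 genes changed at 75 nM and 24 h, 7 in the interaction at 75 nM and 830 in DMSO over time. With only the arrays of the groups compared, which leaves fewer samples, 31 changed at 75 nM and 4 h, 52 at 75 nM and 24 h and 113 in DMSO over time. The replicate block gave 234 at 75 nM and 24 h, 11 in the interaction at 75 nM and 908 in DMSO over time, and an overlap of doses at 24 h of 230. Pairs there correlated at 0.0579 to 0.252 for 75 nM with DMSO at 24 h and -0.0302 to 0.0956 for DMSO over time, not all above 0.1. The cause was not tested for weights or block.

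Without a filter, which tests 22357 genes, 28 changed at 75 nM and 4 h, 18 at 75 nM and 24 h, 123 between doses at 4 h, 0 in the interaction at 75 nM by limma (against 635 at an unadjusted p below 0.05 with the filter) and 103 in DMSO over time. A floor of 7, which tests 4986 genes, gave 616 at 468 nM and 4 h and 2772 at 24 h. Repeated quantile normalization gave 129 at 75 nM and 24 h. The shift by reference genes gave 36 at 75 nM and 4 h, 0 in the interaction at 75 nM by limma and 833 in DMSO over time. The cause was not tested for these rescalings.

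A stricter threshold lowers counts by construction. With at least a 2-fold change 12 and 209 genes remained at 4 h for 75 nM and 468 nM, 15 and 883 at 24 h, 31 and 378 between doses, 1 and 688 interactions and 50 in DMSO over time, with overlaps of doses of 12 and 15. At an adjusted p below 0.01 there were 27 at 75 nM and 4 h, 569 at 468 nM and 4 h, 17 at 75 nM and 24 h, 102 and 1824 between doses, 1 and 1211 interactions and 103 in DMSO over time. With DMSO arrays split, leaving fewer samples, the mean overlap was 17.5 at 4 h and 16 at 24 h.

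Leaving out 1 array gave 39 to 50 genes at 75 nM and 4 h (39 without DMSO 4 h replicate 1 or 2) and 41 to 87 at 75 nM and 24 h (52, 50 and 43 without DMSO 24 h replicate 1, 2 and 3, and 45 and 41 without 75 nM, 24 h replicate 2 and 3). It gave 1 to 5 interactions at 75 nM (1 without DMSO 4 h replicate 1 or 2 or DMSO 24 h replicate 3, and 5 without 75 nM, 4 h replicate 5) and 201 to 548 genes in DMSO over time (201, 247 and 201 without DMSO 4 h replicate 1, 2 and 3, and 217 without DMSO 24 h replicate 2 or 4). The other counts moved by less than 1.5 times.

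Of the tests of lists 29 lost their call with an estimated correlation, 8 with a floor of 7, 8 with fry and 2 with no filter, and 0 with trended and robust moderation, the mean of probe sets, centring, quantile normalization, the block or the shift. Calls gained were 14 with fry, 8 with the shift, 6 with no filter, 5 with the block and 1 each with a floor of 7, centring and quantile normalization. Beyond the calls given for 4 h, the block ended those of NOP2 (0.0527), E2F2 (0.0553), E2F8 (0.0739) and PLK1 (0.0618) at 468 nM and 4 h. Dim genes limit what can be seen, as 9285 of 22357 genes lay above the filter.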

Other observations

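The gene families here were all chosen after the values were seen, so their tests are not independent evidence. Of 18 families tested, 9 are described here for 468 nM and 24 h. Of 18 nuclear pore genes 14 fell (median -0.53, camera adjusted p = 1.17e-05 over 18 families, but adjusted p = 0.124 with an estimated correlation), and their mean was lower than in every DMSO array in 5 of 5 treated arrays. Of 18 centromere protein genes, some of which are also mitosis genes of the lists, 15 fell (median -0.86, camera adjusted p = 1.17e-05, adjusted p = 0.124 with an estimated correlation; lower in 5 of 5 arrays). Among 16 cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, 12 fell and 1 rose (median -0.47, camera adjusted p = 1.26e-04, adjusted p = 0.124 with an estimated correlation; lower in 5 of 5 arrays). YARS1 was at -1.28 ± 0.12 and IARS1 at -0.88 ± 0.08. The folding chaperonin CCT had 6 of 8 genes fallen (median -0.40, camera adjusted p = 0.00846, adjusted p = 0.146 with an estimated correlation; lower in 5 of 5 arrays).

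Other families went different ways. Of 16 histone lysine demethylases 8 rose (median 0.40, camera adjusted p = 0.00303, adjusted p = 0.159 with an estimated correlation), with a mean higher than the DMSO mean in 5 of 5 treated arrays, KDM4A by 0.75 ± 0.09. Of 16 intraflagellar transport genes, which serve the cilium, 7 rose and 1 fell (median 0.46, camera adjusted p = 0.00745, adjusted p = 0.124 with an estimated correlation; higher in 5 of 5 arrays), IFT88 by 0.82 ± 0.13. Mitochondrial ribosomal proteins had 32 of 67 fallen and 3 risen (median -0.30, camera adjusted p = 0.00312, adjusted p = 0.437 with an estimated correlation; lower in 5 of 5 arrays). Cytosolic ribosomal proteins had 9 of 44 fallen and 3 risen (camera adjusted p = 0.936; lower in 4 of 5 arrays), and complex I had 4 of 28 risen and 4 fallen (camera adjusted p = 0.993; lower in 4 of 5 arrays). Of the 9 families left out, 4 passed camera, with kinesins, proteasome and RNA polymerase subunits lower and kelch-like genes higher, and 0 passed with an estimated correlation. The directions of the families that passed camera were the same under each of 3 other scalings.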
